A study of Mus musculus with 16 samples.

How the data were processed

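Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA. The 16 mouse samples fall into 8 stages with 2 samples each: mouse embryonic fibroblasts (MEF, day 0), cells at days 2, 4, 6, 8, 10 and 12 of chemical reprogramming, and the resulting induced pluripotent stem cells (iPSC). Per the labels, the fibroblasts came from embryos of a cross with the OG2 strain. OG2 mice carry a green fluorescent protein transgene driven by Pou5f1 sequences (background knowledge). The iPSC were kept on feeder cells with LIF and inhibitors of GSK3 and MEK, per the labels.

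Per the submitters' processing notes, fastp 0.20.1, Bowtie2 2.2.5, SAMtools, MACS2 2.1.2 and deepTools 3.4.3 were used, with genome build mm10. The notes give no order, role or setting for these tools, and whether reads were shifted for the Tn5 insertion offset is not given in the sources used here. The authors deposited 1 peak list per stage, and how the samples of a stage were combined is not given either. No replicate spread could therefore be computed, no test between stages was run and no p-value is given. Intervals on shares are exact Clopper-Pearson 95% intervals, which cover counting error only.

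The deposited lists hold, per peak, a position, a score, a fold enrichment at the summit, and −log10 p-value and −log10 q-value at the summit, all as the authors' caller wrote them. The score equalled the whole part of 10 times the −log10 q-value for at least 99.994% of the peaks of each list. In the authors' deposited table of each stage, the highest q-value lay between 0.0487 (day 8) and 0.0500 (day 6). These values were used only to rank or filter peaks within a list and to recover pileups.

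Depth per list was not stated and was recovered from the deposited fold (a ratio) and −log10 p-value. The caller's fold is the summit pileup plus 1 over the local background plus 1, and its p-value is a Poisson tail, so the pair of values fixes both the whole-number pileup and the background. Recovered values matched the deposited −log10 p within 0.001 for at least 99.95% of the peaks of each list. The lowest background of a list, here called its background pileup, grows with depth and fragment length. On simulated peaks with known pileups, at least 99.459% were recovered in each of the 8 lists.

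Regions were the union of the 8 lists on chromosomes 1 to 19, X and Y, merged where peaks overlapped by at least 1 bp. Between 36 and 57 peaks per list on other sequences were left out. A region counted as covered in a list if at least 1 bp overlapped a peak. MEF-only regions were covered at day 0 and not in iPSC, iPSC-only regions the reverse, shared regions in both lists, and intermediate-only regions in at least 1 of days 2 to 12 and in neither end point. The chance level of coverage came from 1 seeded random placement of the same widths on the same chromosomes, beyond the first 3 Mb, in place of the planned bedtools shuffle. The base-pair Jaccard index is the length shared by a pair of lists over the length covered by either.

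Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly whose chromosomes mm10 uses, with 21887 protein-coding genes. The table gives no strand, so start sites could not be used as planned. A region was called near a gene end if it lay within 1 kb of either end of a gene, and was assigned to the nearest gene span within 100 kb, which took in 140573 of the 165616 regions. Gene groups were 19 lists with 256 genes, of which 255 were in the table. For each list, the mean over genes of iPSC-only minus MEF-only regions was set against 10000 random lists of the same size, matched in deciles of the number of regions assigned. The percentile describes these lists of peaks and is not a test between stages. Percentiles outside 2.5 to 97.5 are called outside the central range below. The planned motif counts were not run, as no genome sequence was used here.

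The genes named were chosen by a rule fixed before the data were examined. It takes a set of 13 genes of pluripotent cells, fibroblasts, epithelium and endoderm, up to 4 members of each list with the largest difference of iPSC-only and MEF-only regions, the 10 genes with the largest excess of either class, and the 10 with the most intermediate-only regions. Per class, it also takes the 3 regions with the highest score that were not covered in every list. Genes named outside this rule are marked as chosen after their values were seen.

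Alternatives fixed before the data were examined were the better-scored 50% of each list, lists cut to the 31915 best-scored peaks, a stricter overlap rule (the larger part of the region or peak), 200 bp bins, a 2.5 kb gene end window, a 20 kb assignment limit, and the intermediate lists without the longest of them. Chosen after seeing the data were lists thinned to the background pileup of day 8 or of day 12, and counts that leave out doubted lists. For thinning, each summit pileup was drawn once from a binomial distribution with a fixed seed, the local background was scaled alike, and peaks with −log10 p of at least 4 were kept at their deposited ends. Day 12 lies below the day 8 background and was left out of the first. Thinning evens out the background pileup alone. Differences in fragment length, and with them in depth, and in the signal over background between libraries are left.

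Overlap, pileup, gene assignment and random-list steps were tested on simulated data. Of 4000 simulated regions, 100.0% received their class, none of 12000 coverage values differed from bedtools 2.31.1, and none of 500 gene assignments differed from a plain search. Of 200 random lists with no effect, 5.5% fell outside the central range. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.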

Results

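The 8 peak lists held between 31915 peaks (day 12) and 83022 peaks (day 2). Day 0 and iPSC were close to each other, with 49683 and 49520 peaks that covered 34.1 and 34.6 Mb. Their background pileups, 1.96 and 1.90, were also close, so these end points were compared at similar background. The intermediate lists were not: the background pileup was 3.08 at day 2, 1.23 at day 4, 2.12 at day 6, 0.682 at day 8, 0.968 at day 10 and 0.248 at day 12. Coverage by day is therefore given as deposited and, where it matters, at the background pileup of day 8. There were no replicate lists, so every difference below is between single lists.

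The first comparison asked which regions were open in fibroblasts and which in iPSC. Of 165616 regions, 31882 were MEF-only, 32173 iPSC-only and 16877 shared. Shared regions made up 34.6% (95% interval 34.2 to 35.0) of the regions of day 0 and 34.4% (34.0 to 34.8) of those of iPSC. Shared regions lay mostly by gene ends: 58.3% (57.6 to 59.1) were within 1 kb of an end of a protein-coding gene, against 5.96% (5.71 to 6.23) of MEF-only and 8.80% (8.50 to 9.12) of iPSC-only regions. The shares of the latter 2 classes depended on the processing, with 10.2% and 13.9% for a 2.5 kb window and 19.2% and 23.9% at the background of day 12, against 62.6% and 74.7% of shared regions. Of the MEF-only regions 47.9% were in gene bodies and 46.1% between genes, and of the iPSC-only regions 45.0% and 46.2%. The iPSC were grown on feeder cells, and the share of feeders among the cells collected is not given in the sources used here. With lists cut to equal length the counts were 20070 MEF-only and 20182 iPSC-only.

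Genes of the pluripotency network gathered iPSC-only regions. The 24 genes of that list had 137 iPSC-only and 23 MEF-only regions, and 21 of them had more of the former. The mean difference was 4.75 regions per gene, at percentile 100.0 of random lists. Nr5a2, a nuclear receptor gene on chromosome 1 (136842562 to 136960448), had 17 iPSC-only and 0 MEF-only regions. Esrrb, an orphan nuclear receptor of naive pluripotency, had 12 and 2, Zfp42, which encodes the stem cell marker Rex1, had 9 and 0, and Prdm14, a regulator of the naive state and of germ cells, had 8 and 0. Sox2 had 8 and 1, Nanog 5 and 1, Sall4 5 and 1, and Pou5f1 4 and 1. Klf4 had 5 of each class.

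Genes of fibroblasts and mesenchyme showed the opposite. The 26 genes of that list had 146 MEF-only and 49 iPSC-only regions, 22 of them had more MEF-only regions, and the mean difference was −3.73, at percentile 0.0. Runx1, a transcription factor gene of blood and mesenchyme, had 15 MEF-only and 3 iPSC-only regions, Col5a1, a fibrillar collagen gene, 10 and 0, Prrx1, a limb mesenchyme homeobox gene, 9 and 2, and Col1a2 8 and 2. Thy1, a fibroblast surface marker that is lost in reprogramming, had 6 and 1. Twist1 had 0 of either class and Snai2 1 of each, and an end of each of these genes was covered in all 8 lists.

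**Figure D1:**
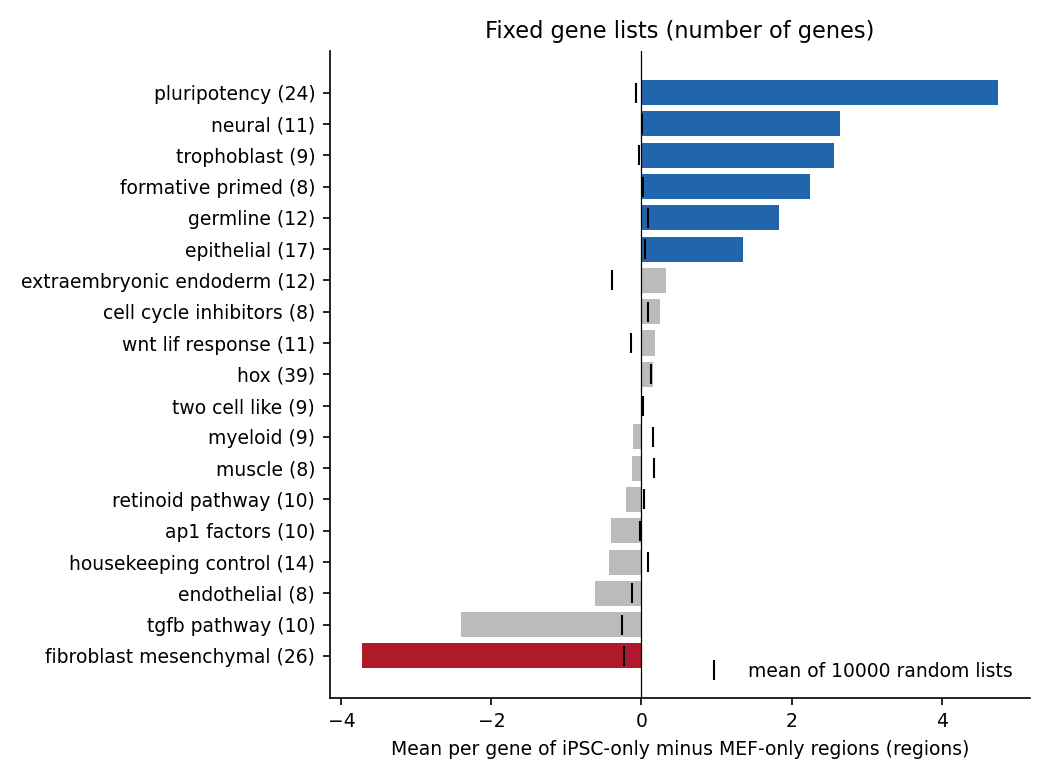
Mean per gene of iPSC-only minus MEF-only regions (x axis, regions) for the 19 fixed gene lists, with the number of genes in parentheses. Blue and red bars lie outside the central range of random lists and black marks are the mean of 10000 random lists; pluripotency stands at 4.75 and fibroblast genes at −3.73.

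Genes of the TGF-beta pathway, which supports the mesenchymal state, had 58 MEF-only and 34 iPSC-only regions, with 8 of 10 members higher in the former. The mean difference was −2.40 at percentile 3.77, inside the central range. It depended on the processing: it was outside with a 20 kb assignment limit (−3.00, percentile 0.560) and with equal list lengths (−2.10, percentile 1.185), inside at the background of day 8 (−1.90, percentile 2.99), and 0.10 (percentile 62.1) at the background of day 12, where no MEF-only excess was left. Smad3 had 13 MEF-only and 3 iPSC-only regions, Ltbp1 19 and 10, and Tgfbr2 7 and 3, while Inhba had 1 and 5. AP-1 factors (−0.400, percentile 31.9) did not stand apart, though they were outside the central range at the background of day 12 (−0.900, percentile 2.385); Fos had 5 MEF-only and 3 iPSC-only regions. The retinoid pathway had a mean of −0.200 (percentile 39.5), with Rarb at 13 and 7. Genes that respond to WNT or LIF had 0.182 (percentile 62.1), with Lef1 at 1 MEF-only and 5 iPSC-only regions. Cell cycle inhibitors had 0.25 (percentile 57.4), with Cdkn2b at 6 and 2, and housekeeping genes −0.429 (percentile 13.6), with Actb at 3 and 1.

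Over all genes, the largest iPSC-only excess was at Tenm4, a teneurin gene (35 iPSC-only and 14 MEF-only regions), followed by Nr5a2, Dpp6 (23 and 7), Arid1b (24 and 9), Clybl, Klf12, Morc1, Msi2, Pard3 and Arl15. The largest MEF-only excess was at Adam12, a metalloprotease gene of mesenchyme (24 MEF-only and 3 iPSC-only), and Aff3 (22 and 1), followed by Cacna1c, Prkg1, Stard13, Dgki, Rbms3, Dlg2, Limch1 and Mrtfa. Mrtfa, a cofactor of serum response factor, had 16 MEF-only and 0 iPSC-only regions. Most of these are long genes, which gather more regions.

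The second comparison followed the MEF-only regions over time. Some of these lay at genes of spermatids and were covered at day 0 alone, and their source stays open (see Other observations). MEF-only regions were covered at 64.1% (63.6 to 64.7) at day 2, 29.0% (28.5 to 29.5) at day 4, 52.4% (51.8 to 52.9) at day 6, 14.4% (13.97 to 14.75) at day 8, 13.0% (12.7 to 13.4) at day 10 and 3.65% (3.44 to 3.86) at day 12. Random placement gave between 1.41% (day 12) and 5.74% (day 2). At matched background pileup the values were 45.8% at day 2, 22.7% at day 4, 34.5% at day 6, 14.2% at day 8 and 11.6% at day 10, so day 4 stayed below day 6, and day 8 below both. The day 0 list itself, thinned alike, covered 62.1% of the MEF-only regions. At the background of day 12, with the classes as reported, day 4 had 9.94% and day 8 7.66%. With classes made anew from end points thinned to that background, day 4 had 24.9%, below day 8 (27.2%) and day 6 (30.1%). Days 10 and 12 had 23.8% and 18.7% in these classes. At that background, whether day 8 lay below day 4 therefore depended on how the classes were made. The iPSC list thinned to it covered 45.0% of shared regions, so shared regions that it missed can count as MEF-only there. Of the 31882 regions, 11888 were last covered at day 6. At Prrx1, 8 of the 9 MEF-only regions were covered at day 2, 6 at days 4 and 6, 0 at day 8 and 1 at day 10. At Smad3, 11 of 13 were covered at day 2, 4 at day 4, 8 at day 6 and 0 at day 8. At Adam12 the numbers at days 2, 4, 6 and 8 were 15, 9, 12 and 1 of 24. Runx1 kept 3 of its 15 at day 8 and Stard13 6 of 22. These counts are as deposited, where day 8 had a lower background pileup than day 6, so part of the fall can reflect depth.

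**Figure D2:**
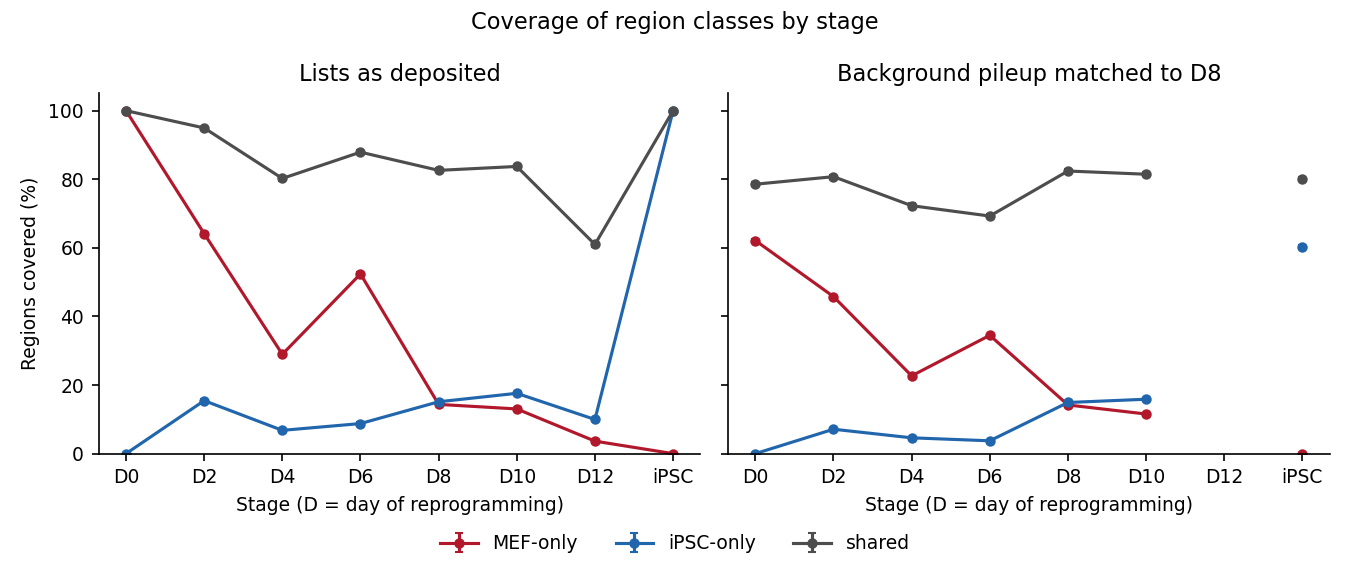
Share of regions covered (y axis, percent, with exact 95% intervals smaller than the points) in each stage list (x axis) for MEF-only, iPSC-only and shared regions, as deposited and at the background pileup of day 8, where day 12 was left out. MEF-only coverage was 52.4% at day 6 and 14.4% at day 8 as deposited.

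The third comparison followed the iPSC regions. Most were in none of the intermediate lists: 21543 of 32173 (67.0%) were covered in iPSC alone. The lists of days 4, 8, 10 and 12 had lower background pileups than iPSC, so low depth can leave such regions out. As deposited, 15.5% (15.1 to 15.9) were covered at day 2, 6.79% (6.52 to 7.07) at day 4, 8.77% (8.46 to 9.08) at day 6, 15.1% (14.7 to 15.5) at day 8, 17.6% (17.2 to 18.0) at day 10 and 9.96% (9.63 to 10.3) at day 12. At matched background pileup they were 7.12% at day 2, 4.61% at day 4, 3.74% at day 6, 14.9% at day 8 and 15.9% at day 10. The iPSC list itself, thinned alike, covered 60.3% of the iPSC-only regions. Shared regions at the same background pileup were covered at 69.3% at day 6 and 82.4% at day 8, so day 8 was also higher for regions open at both end points. With classes made anew at the background of day 12, days 6, 8, 10 and 12 had 11.4%, 30.6%, 29.3% and 28.2%, so most of the fall to day 12 was not seen there. Of 2518 iPSC-only regions first covered at day 8, 817 stayed covered at days 10 and 12.

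Single pluripotency genes differed in timing. An end of Zfp42 was covered at days 8, 10 and 12 and in iPSC, and in none of the earlier lists. The end of Nanog was covered in iPSC alone. Ends of Sox2 and Sall4 were covered in every list but day 12. That list has the lowest background pileup and covered ends of 44.3% of all genes, the lowest share, so their absence there can reflect depth. As deposited, Nr5a2 had 2, 2, 1, 3, 2 and 4 of its 17 iPSC-only regions covered at days 2, 4, 6, 8, 10 and 12. Esrrb had 0, 0, 1, 1, 2 and 1 of 12. The background pileup fell from 3.08 at day 2 to 0.248 at day 12, so these counts cannot show whether coverage changed with time. The highest-scored iPSC-only region lay at chromosome 17, 35503637 to 35506057 (mm10), overlapping an end of Pou5f1, and was covered at days 8, 10 and 12 and in iPSC. Its summit pileup in iPSC was 830 and its fold 5.27, because the local background there was 157. Against the background of the whole list the fold would be 287. The local background at Pou5f1 was also raised in every other list, day 0 included, so levels at this locus cannot be set against those of other genes.

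**Figure D3:**
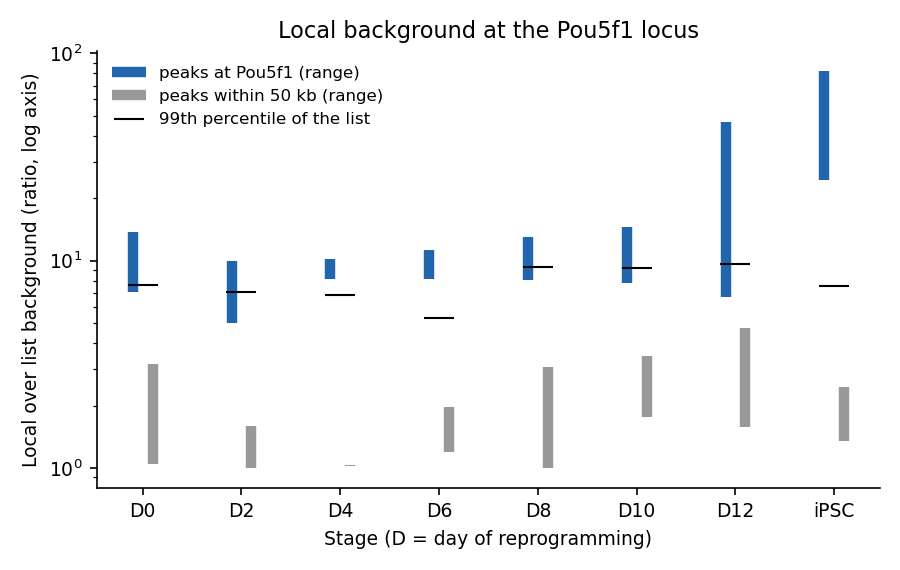
Local background over the list's background pileup (y axis, ratio, log axis) by stage list (x axis), as the range over peaks at Pou5f1 (blue) and over peaks within 50 kb on either side (grey), with the 99th percentile of all peaks (black). In every list the blue range lies above the grey one, from 7.07 to 13.8 at day 0 and from 24.4 to 82.6 in iPSC. The bounds of the locus were set after the values were seen.

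Ends of epithelial genes were covered most often at days 8 and 10. Among the 17 genes of that list, 4 had a covered end at day 0, 10 at day 2, 2 at day 4, 5 at day 6, 14 at day 8, 15 at day 10, 7 at day 12 and 13 in iPSC. At the background pileup of day 8 the numbers were 3 at day 0, 6 at day 2, 1 at day 4, 1 at day 6, 14 at day 8, 14 at day 10 and 9 in iPSC, while all protein-coding genes went from 9568 at day 6 to 12035 of 21887 at day 8. Epcam, which encodes an epithelial adhesion molecule, had a covered end at days 8, 10 and 12 and in iPSC, and not before. Cdh1, the gene of E-cadherin, had a covered end at days 2, 8, 10 and 12 and in iPSC. Grhl2, a regulator of epithelial genes, had 9 iPSC-only regions and 1 MEF-only region, with 2, 0, 2, 5, 3 and 0 of the former covered at days 2 to 12, and Dsp, a desmosome gene, 6 and 1. Krt18 went the other way, with 5 MEF-only regions and 1 iPSC-only region. The list's mean difference was 1.35 (percentile 98.7), and it was inside the central range with a 20 kb limit (0.824, percentile 93.9) and at the background of day 12 (0.588, percentile 96.9).

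Ends of pluripotency genes were covered in 8 of 24 at day 0, 12 at day 2, 8 at day 4, 12 at day 6, 13 at day 8, 15 at day 10, 11 at day 12 and 19 in iPSC. With matched background pileup these were 5 at day 0, 11 at day 2, 6 at days 4 and 6, 13 at day 8, 14 at day 10 and 15 in iPSC. Ends of fibroblast genes were covered in 21 of 26 at day 0, 22 at day 2, 19 at day 4, 22 at day 6, 15 at days 8 and 10, 9 at day 12 and 17 in iPSC. At matched background pileup they were 16 at day 0, 18 at day 2, 14 at day 4, 16 at day 6, 15 at days 8 and 10 and 11 in iPSC. At the background of day 12 they went from 4 at day 6 to 12 at day 8, while all gene ends went from 5631 to 10510, so the direction from day 6 to day 8 turned with thinning. Housekeeping gene ends were covered in 12 of 14 at day 0, 13 at days 2, 6 and 8, 12 at days 4 and 10, 8 at day 12 and 12 in iPSC.

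**Figure D4:**
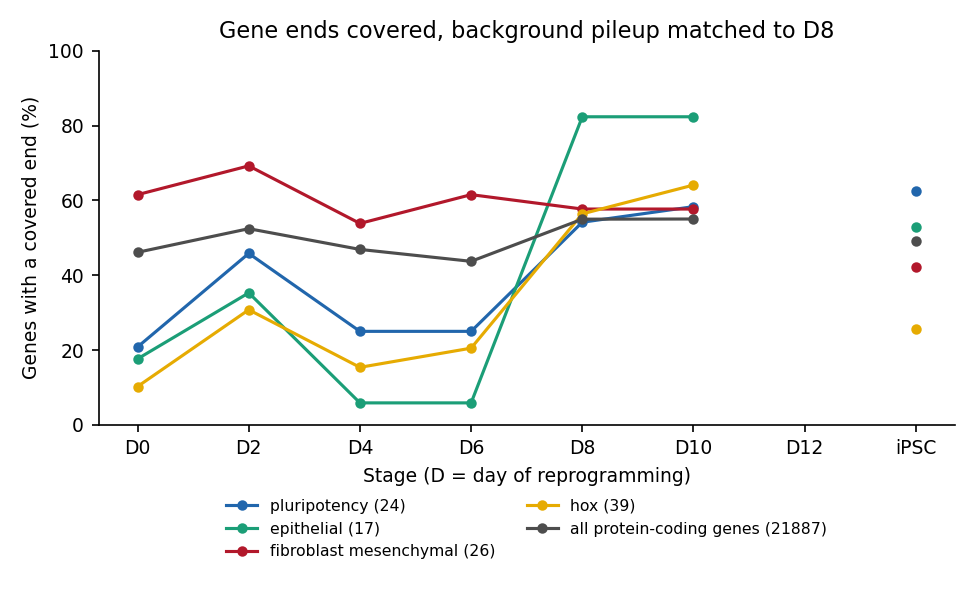
Share of genes with an end covered (y axis, percent) by stage list (x axis) at the background pileup of day 8, for 4 fixed lists and all protein-coding genes, with the number of genes in parentheses. Epithelial genes went from 1 of 17 at day 6 to 14 of 17 at day 8.

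The fourth comparison concerned regions covered in intermediate lists alone. This class draws on 6 lists. The day 2 list has a higher background pileup than both end points, so absence from those can reflect depth. Of the 41136 intermediate-only regions at day 2, 20432 (49.7%) were in no other list. Intermediate-only regions were the largest class, with 84684 regions (51.1%), of which 4.20% (4.07 to 4.34) lay near a gene end. In 20338 of them coverage held in adjacent intermediate stages, and 16996 were in at least 2 of days 2 to 6 and in none of days 8 to 12. The reverse set, in at least 2 of days 8 to 12 and in none of days 2 to 6, had 7295, but the lists of days 8 to 12 have the lower background pileups. Intermediate-only regions at matched background pileup were covered at 24.3% at day 2, 12.3% at day 4, 11.4% at day 6, 17.9% at day 8 and 18.6% at day 10. The class was made from the lists as deposited, so regions found only in the deeper day 2 list stay in it and can raise the day 2 value. Day 12 had the highest share seen in no other list, 11919 of its 16465 intermediate-only regions (72.4%), and 16.7% of its peaks had the lowest summit pileup of 3. Genes with the most such regions were Macrod2 (88), Rbms3 (84), Auts2 (77), Rad51b (77), Pde4d (74), Robo1 (72), Nav2 (65), Pcdh15 (63), Sox5 (62) and Cdh13 (61), all long genes. At Pcdh15, 25 were in at least 2 of days 2 to 6 and in none of the later days, and 0 in the reverse set. At Foxa2, a gene of endoderm, the numbers were 1 and 9 of 21.

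Among intermediate-only regions, the highest score at day 2 was at chromosome 8, 110676471 to 110677380, inside Vac14, covered at days 2, 4 and 6. The next were at chromosome 1, 190532776 to 190533879, with no protein-coding gene within 100 kb (days 2 to 10), and at chromosome 16, 96034168 to 96035393, inside Brwd1 (days 2, 4, 6 and 10). The other iPSC-only regions of highest score were at chromosome 6, 146855268 to 146855764, inside Smco2 (days 8 and 10 and iPSC), and at chromosome 10, 120216815 to 120217314, inside Tmbim4 (iPSC alone). Among shared regions the highest score at day 0 was at chromosome 16, 11517448 to 11519388, inside Snx29. The next lay between genes, 4361 bp from D7Ertd443e and 41648 bp from Pfkfb3. The 3 MEF-only regions of highest score lay at genes of spermatids: Prm1 (chromosome 16, 10796326 to 10796909, fold 25.4), Prm2 (10791380 to 10791972, fold 10.1) and Smcp (chromosome 3, 92583864 to 92584443, fold 22.4). All 3 were covered at day 0 alone.

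The last comparison set neighbouring stages side by side. From day 6 to day 8, 35627 regions were lost and 18985 gained, and 12982 of those lost were MEF-only. At matched background pileup the loss was 18806 and the gain 23664, so the net direction turned. Shared regions were covered at 69.3% at day 6 and 82.4% at day 8 there, so unequal sensitivity can enter this turn. The Jaccard index of days 6 and 8 was 0.217, against 0.441 for days 8 and 10, 0.377 for days 4 and 6, 0.325 for days 0 and 2, 0.287 for days 2 and 4, 0.224 for days 10 and 12 and 0.128 for day 12 and iPSC. At the background of day 12, day 12 and iPSC (0.154) and days 6 and 8 (0.196) had the 2 lowest values of neighbours. Thinning kept the peak ends, so differences in peak width are left in this index. As deposited, the median width was 264 bp at day 12 and 609 bp in iPSC. The lists covered 10.4 and 34.6 Mb, which by itself keeps their index low. To day 0 the index was highest at day 6 (0.372), ahead of day 2 (0.325) and day 4 (0.289), and was 0.217 at day 8. To iPSC it was highest at day 10 (0.240), with 0.223 at day 8 and 0.173 at day 6. From day 12 to iPSC, 35554 regions were gained and 17627 lost as deposited, and 8623 gained and 19000 lost at the background of day 12, so the net direction turned with thinning. At that background the day 12 list covered 60.2% of shared regions and the iPSC list 45.0%. The thinned lists were thus not equally sensitive for these, and neither net direction can be read as opening or closing.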

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

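Every test in this part was chosen after the result was seen. A raised local background at Pou5f1, a signal apart from the positions of peaks, stood out in the day 0 list, where it reached 13.8 times the background pileup of the list. The peaks at chromosome 17, 35500588 to 35517367, had ratios from 7.07 to 13.8, against 1.04 to 3.17 for peaks within 50 kb and 7.66 at the 99th percentile of all day 0 peaks. In 8 of 8 lists all ratios inside the locus exceeded all flanking ones. The bounds of the locus were set after the values were seen, so this count follows in part from their choice. Extra copies of the Pou5f1 fragment, as an OG2 transgene would bring, could raise the background in all lists, though clustered open chromatin would do the same. For the latter, called peaks held at most 47.8%, 88.9% and 111% of the local background at the 3 day 0 peaks (median 88.9%), against a median of 79.1% at 730 other peaks with a ratio of at least 7, so these 2 explanations cannot be told apart by the upper limits that a peak list allows. The ratios of 6.71 to 46.6 at day 12 and of 24.4 to 82.6 in iPSC may include opening of the locus, with or without extra copies. A biological difference between stages stays open as untested.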

How the results depend on the processing

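The thinned lists and the counts without doubted lists were chosen after seeing the data. No paired analysis was possible because each stage has 1 pooled list and no test was run. Leaving out replicates was not possible for the same reason, and motif counts were not run. The stricter overlap rule moved nothing by construction, since every peak lies within its region. The pluripotency and fibroblast lists kept their sign and stayed outside the central range under the 4 alternatives run. MEF-only coverage stayed lower at day 4 than at day 6, and iPSC-only coverage higher at day 8 than at day 6, under all alternatives run. The background pileup of day 12 was the lowest, which limits values at that day: thinned to it, the lists of day 0 and iPSC covered 25.8% of MEF-only and 24.1% of iPSC-only regions, and those of days 8 and 10 covered 69.9% and 65.6% of shared regions. A count is called moved beyond a factor of 1.5, a share outside its counting interval, and a Jaccard index if its rounded value changed. Of the main results, such as class sizes and lists outside the central range, 76 values moved, 44 did not and 5 list means came inside that range. Of the values for single days, neighbours and remaining lists, 99 moved, 68 did not and 3 list means moved outside the central range. Values under the stricter overlap rule count as not moved. The 3 means were those of TGF-beta pathway genes with a 20 kb limit (−3.00) and with equal list lengths (−2.10), and of AP-1 factors at the background pileup of day 12 (−0.900). At that background the mean of the TGF-beta list was 0.10, against −2.40. Where the construction of an alternative does not show the cause of a change, the cause was not tested.

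With the better-scored 50% of each list the classes held 15594 MEF-only, 15551 iPSC-only, 9137 shared and 36407 intermediate-only regions, as fewer peaks entered. MEF-only coverage was 27.6%, 55.6% and 13.8% at days 4, 6 and 8, iPSC-only coverage 8.35% and 17.1% at days 6 and 8. The Jaccard index was 0.394 for day 6 to day 0, 0.275 for day 10 to iPSC and 0.245 for days 6 and 8, with 8810 regions gained and 17592 lost between the latter.

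With equal list lengths there were 20070 MEF-only, 20182 iPSC-only and 51535 intermediate-only regions. MEF-only coverage was 33.3%, 50.3% and 17.6%, iPSC-only coverage 6.18% and 20.6%. The index was 0.392, 0.266 and 0.241 in the same order, and 17586 regions were lost and 17256 gained from day 6 to day 8. Near gene ends lay 7.44% of MEF-only, 12.4% of iPSC-only, 68.4% of shared and 5.22% of intermediate-only regions. With a 2.5 kb window these were 10.2%, 13.9%, 62.6% and 8.42%.

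With 200 bp bins, a finer unit, there were 116154 MEF-only, 118260 iPSC-only, 54309 shared and 287033 intermediate-only bins. MEF-only coverage was 22.2%, 42.8% and 9.03%, iPSC-only coverage 7.07% and 10.0%.

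At the background pileup of day 8, with classes made anew, 11070 regions were shared. MEF-only coverage was 30.8%, 45.0% and 21.5%, iPSC-only coverage 8.25% and 22.6%. The index was 0.349, 0.246 and 0.226, and 18806 regions were lost and 23664 gained from day 6 to day 8. The longest list was 1.60 times the shortest, against 2.60 as deposited. Near gene ends lay 8.91%, 12.4%, 66.8% and 5.85% of the classes in the order above.

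At the background pileup of day 12 there were 11442 MEF-only, 11238 iPSC-only, 4130 shared and 47860 intermediate-only regions. MEF-only coverage was 24.9%, 30.1% and 27.2%, so the drop from day 6 to day 8 nearly vanished where the classes were made from thinned end points, and it was 14.7% to 7.66% with the classes as reported. iPSC-only coverage was 11.4% and 30.6%. The index was 0.233, 0.213 and 0.196, and 7980 regions were lost and 17412 gained from day 6 to day 8, the reverse of the net loss as deposited. Thinned alike, the day 6 list covered 38.6% and the day 8 list 69.9% of the shared regions as reported, so unequal sensitivity can enter. Near gene ends lay 19.2%, 23.9%, 74.7% and 10.7%. Here 4 lists came inside the central range: epithelial (0.588, percentile 96.9), trophoblast (0.444, 81.8), germline (0.417, 91.6) and neural (0.727, 97.2). The epithelial list did so with a 20 kb limit too (0.824, percentile 93.9).

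Of the iPSC-only regions, 10630 were also covered in a list of days 2 to 12, and of the MEF-only regions 22691. Without day 2 there were 66350 intermediate-only regions, and without day 12 there were 72826.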

Other observations

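Of the tests in this part, that on 25 further germ cell genes was chosen before its result was seen, and the others after. Beyond pluripotency, genes of other early lineages gathered iPSC-only regions. The neural list had 43 iPSC-only and 14 MEF-only regions (mean difference 2.64, percentile 99.9), with Sox1 at 10 and 2, Olig2 at 5 and 0 and Zic1 at 4 and 0. The trophoblast list had 31 and 8 (2.56, percentile 99.5), led by Tfap2c at 10 and 1 and Elf5 at 6 and 0. The formative list had 27 and 9 (2.25, percentile 98.4), where Foxd3 had 11 and 1 and Otx2 7 and 1, while Fgf5, a gene of the epiblast after implantation, had 0 and 4. The germline list had 28 and 6 (1.83, percentile 99.6), with Prdm1 at 11 and 5 and Dppa3 at 4 and 0. At the background of day 12 the trophoblast, germline and neural lists were inside the central range.

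Other lists did not stand apart. Extraembryonic endoderm had a mean difference of 0.333 (percentile 72.4), in which Foxa2 had 9 iPSC-only and 2 MEF-only regions, Gata6 6 and 0 and Gata4 3 and 2, against Col4a1 with 3 and 10. Endothelial genes had −0.625 (percentile 33.6), myeloid genes −0.111 (percentile 30.3), muscle genes −0.125 (percentile 25.4) and Hox genes 0.154 (percentile 54.9). The 2-cell list had 0 regions of either class in its 9 genes, which lie in repeated clusters. Hox gene ends were covered in 13 of 39 at day 0, 28 at day 2, 9 at day 4, 23 at day 6, 22 at day 8, 25 at day 10, 9 at day 12 and 19 in iPSC. With matched background pileup they were 4, 12, 6, 8, 22 and 25 at days 0 to 10 and 10 in iPSC, while ends of all genes went from 9568 at day 6 to 12035 at day 8.

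Some genes of haploid male germ cells were covered at day 0 alone, namely 14 of 15 whose values were seen before any test (Crisp2 was also covered at days 4 and 8), among them Prm1 (summit pileup 300), Prm2 (207), Tnp2 (153), Smcp (123), Hmgb4 (120) and Tnp1 (75). Of the genes named, Crisp2, Tnp2, Hmgb4 and Tnp1, and below Hils1, H1f7, Gk2, Txndc2 and Lelp1, were named after their values were seen. DNA of haploid germ cells in a day 0 library is a candidate source. Among 25 further genes of such cells, 5 (20%, 95% interval 6.83 to 40.7) had an end covered at day 0 alone, namely Hils1, H1f7, Gk2, Txndc2 and Lelp1, against 0.608% of all genes. A further 6 were covered at day 0 and in other lists. The 20% lies at, and not above, the level set in advance for that source, so it stays open. Of the 13 further genes covered in no other list, 5 (38.5%, interval 13.9 to 68.4) had an end covered at day 0. The level set in advance was for all 25 genes. A general opening of germline genes stays open too. Of 25 germline and oocyte genes, 6 had an end covered at day 0, each also in another list, and of the 8 covered in no other list 0.0% (interval up to 36.9) had one covered at day 0, which are too few genes to decide. The labels give embryonic fibroblasts, which hold no such cells, and no other biological explanation was tested.

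MEF-only coverage was lower at day 4 than at day 6. Lower depth at day 4, as far as the background pileup shows it, is argued against by 22.7% at day 4 and 34.5% at day 6 at matched background pileup. A day 4 list less sensitive for every class is argued against by shared regions, covered at 72.3% at day 4 and 69.3% at day 6. Shared regions lay mostly by gene ends and MEF-only regions did not, so lower sensitivity for regions like the latter is not excluded. The iPSC-only and intermediate-only classes, also mostly away from gene ends, had 4.61% and 12.3% at day 4 and 3.74% and 11.4% at day 6. Whether an exchange of the labels accounts for it stays open. Over the 116857 regions not covered at day 0, where MEF-only regions take no part, the summed Jaccard index of neighbours, counted in regions, was 0.522 for the order 2, 6, 4, 8 and 0.519 as labelled at matched background pileup, and the 95% interval of the difference over resampled regions (−0.00294 to 0.00985) holds 0. The difference was 0.067 (0.0619 to 0.0719) as deposited and −0.0124 (−0.021 to −0.00403) at the background of day 12, so its sign turned with thinning. These intervals do not cover the spread between libraries. Over whole lists in base pairs, the exchanged order was higher by 0.132 as deposited, 0.075 at the day 8 background and 0.043 at the day 12 background. That measure takes in the MEF-only regions in which the pattern was seen, so it cannot decide the question. A passing closure and reopening of fibroblast regions, for which the labels give the days as groups, stays open as untested.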
